A study of Mus musculus with 4 samples.

How the data were processed

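The 4 samples are the gene expression and surface antibody measurements of 2 libraries of cells sorted from mouse CT26 tumours treated with anti-PD-1 and anti-LAG-3, 1 library from responding and 1 from non-responding tumours. Per the labels, mRNA was captured with 10x Genomics single cell chemistry from the 3′ end and antibody tags were sequenced beside it. The deposited matrices hold raw UMI counts per gene or antibody and cell barcode, made by the authors with bcl2fastq and Cell Ranger against mm10 and, per the file headers, Cell Ranger 6.0.1. They hold no further normalization and only barcodes that had passed the authors' cell calling. The gene annotation's version was not stated and the files give no gene coordinates, so genes are identified by symbol and Ensembl identifier. Each matrix holds 32285 genes and 12 antibodies. UMIs of 38 symbols that stand for more than 1 identifier were kept apart by identifier.

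Cells were kept with at least 1000 gene UMIs, at least 500 detected genes and under 10% mitochondrial UMIs. Doublets were scored within each library with Scrublet in scanpy. Its automatic threshold called 1 and 0 cells, so a score limit was set instead at the top 0.8% per 1000 barcodes, which is the top 6.02% in the non-responding and 6.23% in the responding library. The cells that scored above it were left out, 356 of 6646 (5.36%) and 340 of 6400 (5.31%), fewer than the target because 71 and 83 cells had a score equal to the limit and were kept. Foxp3 and a Cd8 gene were detected together in 11.5% and 9.41% of the cells left out, against 3.29% and 2.56% of the rest. Counts were scaled per cell and log-transformed, and 2000 variable genes were picked over both libraries. Of these, 1735 were used to cluster. T cell receptor, immunoglobulin, mitochondrial, ribosomal protein and histone genes, Xist, and members of the program lists other than class markers were left out. This kept most list genes compared later from entering the clustering directly. Class markers, such as Gzma, Prf1 and Eomes, and genes outside the lists could stay in. Clusters led by interferon or cell cycle genes still formed, so the clusters are not independent of these programs. Leiden clustering used 40 principal components, 20 neighbours and resolution 1.0, and clusters with a mixture of Cd4 and Cd8 were clustered again with 20 components. No correction between libraries was applied.

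Clusters, not single cells, were named. A T cell cluster needed a Cd3e level of at least 300 UMIs per 1000000 gene UMIs (CPM). It was called Treg-like with Foxp3 at 100 CPM or more and Cd8 under 300 CPM. It was called CD8 T-like with a summed Cd8a and Cd8b1 level of 300 CPM or more, at least 5-fold over Cd4, and Cd4 under 50 CPM. It was called CD4 conventional T-like with Cd4 at 100 CPM or more, at or above Cd8, and Cd8 under 150 CPM. Each name also needed 3 markers of its list at 20 CPM or more. A cluster whose leading genes held more markers of natural killer or innate lymphoid cells than of its own class was kept out of that class. The cluster thresholds, the choice of clustering genes and the doublet share were set after the counts had been seen. The comparisons, the 19 program lists, the 14 marker lists and the rule for named genes were set before the data were examined. Of the program and marker lists, 3 genes (Aldoa, Mx1 and Mx2) were not among the measured features under those symbols.

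Within each class, UMIs were summed per library and divided by all gene UMIs of the class to give CPM. A gene counted as measured at 20 CPM or more in either library. Ratios are responding over non-responding. With 1 library per group no test of the groups was possible and none was made. Intervals are exact 95% intervals, Clopper-Pearson for shares and the conditional binomial for ratios of counts. The fold between shares of cells has a log-normal (Katz) interval. All of them cover counting error only, not differences between animals or library preparations. Intervals for UMI sums also leave out the uneven spread of UMIs over the cells of a library. In each class the rule named up to 12 (Treg-like) or 8 (other classes) genes with the highest ratio, and as many with the lowest, among those whose interval lay wholly beyond 1.5-fold. Immunoglobulin, receptor segment, mitochondrial and ribosomal protein genes, Xist, Y-linked genes and gene models without a symbol of their own were counted but not named by it. Foxp3, Ifng, Pdcd1, Lag3 and Cd274 were given in every class, and up to 4 list members each way per list. A list member was called higher or lower when its ratio was at least 1.5-fold and its interval excluded 1. The median log2 ratio of a list has an interval from 1000 Poisson draws and a percentile among 10000 random lists of genes matched on expression from the 50 nearest genes, as a description of these libraries. Shares of cells with a UMI were taken after thinning each cell to 3000 UMIs, and cells with fewer were left out. Random steps used seed 1.

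Antibody counts were compared between classes within each library, as ratios of mean counts per cell, because the libraries differed in antibody depth. The counting step was tested on simulated data made from the Treg-like sums, with 200 of 5955 genes given a fold. At 2-fold, the interval excluded 1 for 100% of 50 genes and lay beyond 1.5-fold for 90% of them. It held 1 for 96.0% of the genes without a fold. Sums hold no spread of UMIs between cells, so the simulation does not check the intervals against that spread.

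Alternatives tried were classes from each cell's own UMIs, doublets kept, a lower (0.5) and a higher (1.5) resolution, clustering without Treg genes, a mitochondrial limit of 5%, measurement at 10 or 50 CPM, median-of-ratios scaling, CPM without ribosomal protein, mitochondrial and receptor genes, a mean over cells, genes 3-fold higher in non-T cells left out, proliferating cells left out, other proliferation thresholds, and centred log ratios of antibody counts. Others were added later and are named as such in the closing part. Clusters of other cells and unnamed clusters were left out of the gene comparisons. The tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.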

Results

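Cells were sorted from CT26 tumours, a mouse colon carcinoma line grown under the skin, of animals given antibodies against the checkpoint receptors PD-1 and LAG-3. Both antibodies were given into the abdomen on days 7, 10 and 13 after implantation, at a labelled concentration of 1 mg/mL each, and tumours were taken on day 15. The 4 samples are gene expression and surface antibody measurements of 1 non-responding and 1 responding library. How response was judged and how many animals each library holds are not in the labels. The gene matrices held 62003310 UMIs over 7530 barcodes in the non-responding library and 54681448 UMIs over 7784 barcodes in the responding one. Of these barcodes, 11.7% and 17.8% fell below the cell filter, and 6290 non-responding and 6060 responding cells were used, with medians of 7760 and 7207.5 UMIs and of 2387 and 2251 genes. Antibody depth differed 65.1-fold, with 2533563 counts in the non-responding and 38914 in the responding library. With a single library per group there is no replicate check on any difference given here.

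The sample labels give the sort as CD45+CD11b- and the study's design text adds CD3+ and CD19-, and which of these applied is not known, so the shares below are of all used cells. The first comparison asks how the sorted cells divided into classes, and how CD8 T cells stood to regulatory T cells, the subject of the study's title. Treg-like cells, named by Foxp3, the transcription factor that marks regulatory T cells, made up 21.1% (20.1 to 22.1) of non-responding and 13.4% (12.6 to 14.3) of responding cells, a fold of 0.638 (0.589 to 0.691). CD8 T-like cells made up 20.4% (19.4 to 21.4) and 26.6% (25.5 to 27.7), a fold of 1.31 (1.22 to 1.39). The ratio of CD8 T-like to Treg-like cells was 0.968 (0.895 to 1.046) in the non-responding and 1.98 (1.82 to 2.15) in the responding library. CD4 conventional T-like cells made up 34.6% and 37.3%, a fold of 1.08 (1.03 to 1.13). Gamma-delta T-like cells made up 1.38% and 0.825%, a fold of 0.597 (0.422 to 0.843).

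Several clusters entered no class. A cluster kept out of the CD4 class, led by Il1rl1, the interleukin-33 receptor, with Pparg and Hdc, held 5.20% of non-responding and 2.49% of responding cells, a fold of 0.479. It met the thresholds of the CD4 class. It was kept out because Il1rl1, on the innate lymphoid list, was among its leading genes and no CD4 marker was. Its surface CD4 counts stood at 0.910 and 0.760 of those of the CD4 class. With it in, the CD4 shares of the libraries would be nearly equal, so the fold of 1.08 depends on leaving it out. Clusters kept out of the CD8 class held 4.10% and 3.22%, a fold of 0.785. The main one, led by Dapl1 and the lymph node homing genes Sell and Ccr7, held 3.70% and 2.81%, a fold of 0.757, and the other, led by Trim30c, Cxcl10 and Rsad2, held 0.397% and 0.413%. Both met the thresholds of the CD8 class. They were kept out because Eomes, on the natural killer list, was among their leading genes and no CD8 marker was. With them in, the CD8 fold of 1.31 would be smaller and both CD8 to Treg ratios higher. Memory and naive genes of the CD8 class are compared without them. Macrophage-like cells held 0.366% and 0.182%, although CD11b-positive cells were sorted out. Unnamed clusters held 12.9% and 15.9%, a fold of 1.24. The largest of them, led by the natural killer receptor genes Klra5 and Ncr1 with Trdc, held 7.66% and 10.2%, a fold of 1.33. When each cell was classed from its own UMIs, the fold of CD4 conventional T-like cells turned to 0.934, and the 2 CD8 to Treg ratios stood at 1.72 and 3.66.

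**Figure D1:**
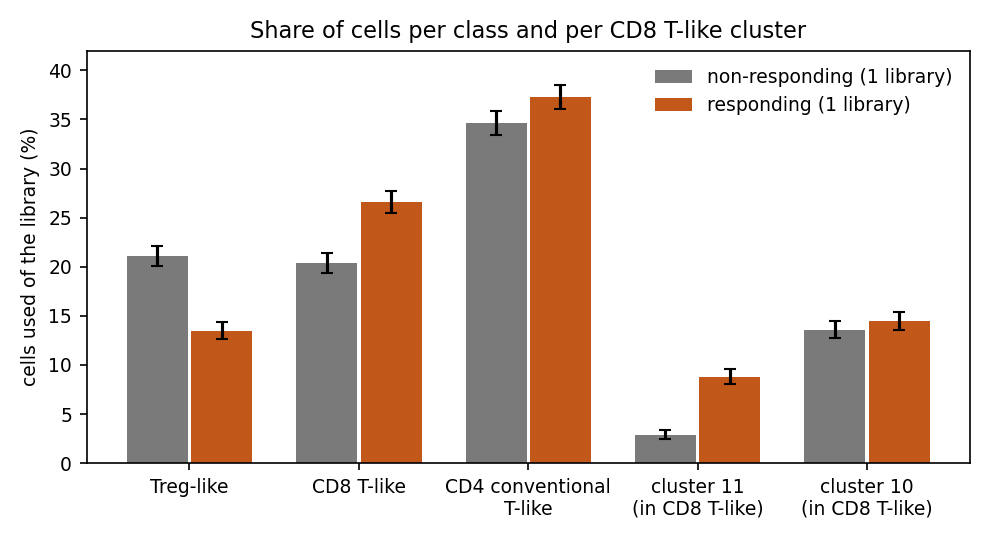
Share of cells used (percent) in the 3 T cell classes compared and in clusters 10 and 11 of the CD8 T-like class, in the non-responding and the responding library, with exact 95% intervals for counting error. Treg-like cells stood at 21.1% and 13.4%, and CD8 T-like cells at 20.4% and 26.6%.

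The CD8 T-like class held an uneven cluster, here cluster 11, set apart by Slc17a6, Prf1, Klre1, Srgap3 and Havcr2, which are therefore not results of their own in it. It held 2.89% (2.49 to 3.34) of non-responding and 8.81% (8.11 to 9.55) of responding cells, that is 182 and 534 cells and a fold of 3.05 (2.58 to 3.59). It was 14.2% (12.3 to 16.2) of the non-responding and 33.1% (30.8 to 35.5) of the responding class. Most of its cells come from the responding library, so it may be a feature of that library. All cells were clustered again without 40 genes, the leading genes of cluster 11 and those with intervals beyond 1.5-fold between the libraries in the whole class. The matching cluster then held 96.2% of the cells of cluster 11 and had a fold of 3.11, but other genes that distinguish it may have stayed in. With doublets kept, the best match was a piece of a cluster that had been split again as a mixture of Cd4 and Cd8. That piece held 24.9% of the cells of cluster 11 and had a fold of 1.75, so this setting cannot tell whether they stay together. Cluster 10, led by Gzmk and Ccl5, held 13.6% and 14.4% of all cells, a fold of 1.06 (0.972 to 1.16).

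The next comparison asks which genes differed in Treg-like cells, since the title speaks of their reprogramming. The sums rest on 1325 non-responding cells with 8412616 UMIs and 815 responding cells with 4522864 UMIs. Ccl4 (ENSMUSG00000018930), a chemokine that draws CCR5-bearing cells, was higher in the responding library by 6.77-fold (5.50 to 8.38). Ifng (ENSMUSG00000055170), which encodes interferon gamma, was 2.91-fold higher (2.09 to 4.10). Gzmb (ENSMUSG00000015437), the cytotoxic protease granzyme B, was lower, at a ratio of 0.620 (0.586 to 0.656), 579 against 359 CPM. Hspa1b (ENSMUSG00000090877), a heat-inducible chaperone, stood at 0.259 (0.182 to 0.359). Outside this class it was also called lower in clusters 0, 3, 7, 9, 14 and 15, but not in clusters 2, 8, 10, 11 and 13. Of 5955 measured genes, 99.3% lay within 1.5-fold, 7 were at least 2-fold higher and 1 was at least 2-fold lower. These counts depend on the processing. They were 11 and 9 with measurement at 10 CPM, and 12 and 7 with classes from each cell's own UMIs.

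The rule named 6 higher and 2 lower genes. Besides Ccl4 and Ifng the higher ones were Trdc, the constant segment of the gamma-delta receptor, at 4.41 (3.06 to 6.46), the metallothionein Mt1 at 2.99 (2.28 to 3.94), the interferon-induced membrane protein Ifitm1 at 2.77 (2.18 to 3.53), and Art2b at 2.29 (1.71 to 3.07). Single cells weighed on several of these. For Ccl4, 282 of 422 responding UMIs lay in 1 cell, and without each library's highest cell the ratio was 3.01 (2.29 to 3.98). For Ifitm1, 131 of 176 lay in 1 cell and the ratio without it was 1.24 (0.830 to 1.83). Without the highest cells Ifng stood at 2.15 (1.46 to 3.17), Trdc at 2.92 and Mt1 at 2.34. Leaving out cells with 2 or more thinned UMIs of the proliferation list turned Trdc to -0.87 and Mt1 to -0.97 on the log2 scale. Such cells were 79.4% of Treg-like cells in both libraries, as the list holds broadly expressed genes, so this step removed most cells. Foxp3 itself, which named the class, was at 0.821 (0.780 to 0.865), Lag3 at 1.78 (1.48 to 2.14), Pdcd1, which encodes PD-1, at 1.11 (0.974 to 1.27), and Cd274, which encodes its ligand PD-L1, at 0.977 (0.869 to 1.1). Igkc at 0.522, Gm10260 at 1.89 and Gm10076 at 2.59 also lay beyond 1.5-fold but are outside the rule and were chosen after their values were seen.

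**Figure D2:**
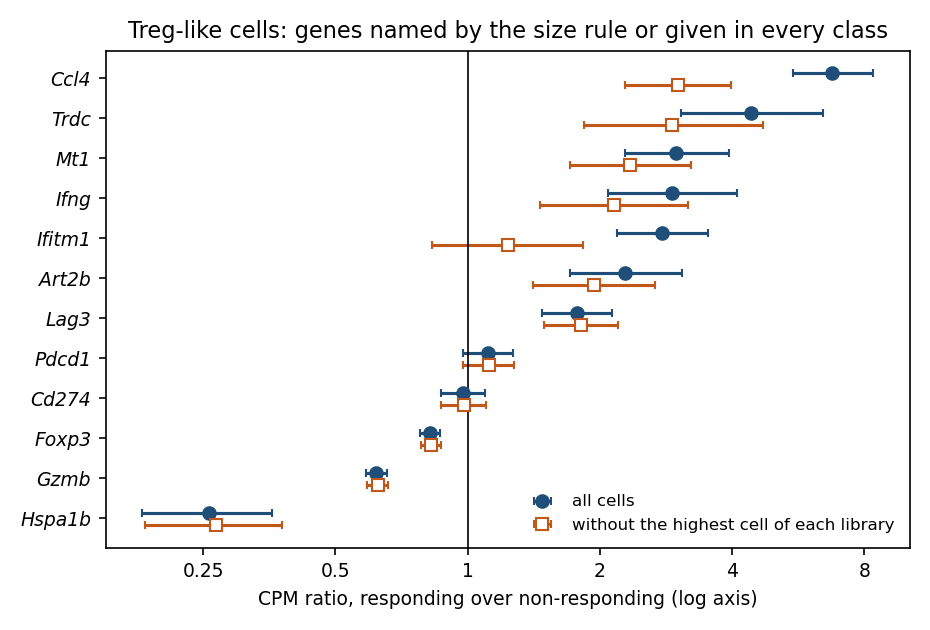
Responding over non-responding ratio of CPM (log axis) of named genes in Treg-like cells, with exact 95% counting intervals, for all cells and without the highest cell of each library. Ccl4 stood at 6.77 and at 3.01, Ifitm1 at 2.77 and at 1.24.

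Shares of Treg-like cells with a UMI were compared after thinning to 3000 UMIs, which left out 61 non-responding and 56 responding cells. Median depths before thinning were 5691 and 4988 UMIs. Foxp3 was found in 68.0% (65.4 to 70.6) of non-responding and 64.4% (60.9 to 67.8) of responding cells, against 80.5% and 73.5% unthinned. In CD8 T-like cells, taken as the background for Foxp3 at median depths of 10218 and 9513 UMIs and with 16 and 53 cells left out, the thinned shares were 0.711% and 0.577% and the unthinned ones 1.95% and 1.24%. Gzmb was found in 37.6% and 32.0% of Treg-like cells, 46.3% and 37.9% unthinned. Ccl4 was found in 1.66% (1.03 to 2.53) and 4.74% (3.34 to 6.51), 2.79% and 6.50% unthinned. Ifng was found in 1.82% and 2.77%, 3.77% and 4.91% unthinned, so that its thinned intervals overlapped. CD4 conventional T-like cells, at median depths of 6766 and 6006.5 UMIs and with 90 and 160 cells left out, held Ccl4 in 2.44% and 2.28% and Ifng in 6.08% and 7.56%. Unthinned, those cells held Ccl4 in 4.45% and 4.60% and Ifng in 11.2% and 12.4%. No class here is known to lack Ccl4, Ifng, Gzmb, Lag3 or Pdcd1, so Foxp3 gives the only background share.

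By list, the Treg identity genes as a group had a median log2 ratio of -0.12 (-0.17 to -0.066) over 13 measured members, at percentile 0.745 of matched random lists, with no member called. The marker genes among them named the class, and Il2ra stood at 0.753, Itgae at 0.805, Ctla4 at 1.01 and Gpr83 at 1.21. Of 13 suppression genes, 12 lay below 1 and the median was -0.18 (-0.25 to -0.084), at percentile 0.01. Only Gzmb was called, and Tgfb1, an inhibitory cytokine, stood at 0.759, Fgl2 at 0.835 and the ectonucleotidase Entpd1 at 1.09. Type I interferon response genes had a median of -0.20 (-0.26 to -0.13) over 21 members, 19 of them below 1, with Ifit3b called lower at 0.636. Genes of interleukin-2 and STAT5 signalling had a median of -0.22 (-0.29 to -0.16) over 12 members, with Lta called lower at 0.598, Osm at 0.697 and Il2ra at 0.753. None of the 10000 matched random lists had a lower median than these last 2 lists. Of 12 Th1-like genes, Ifng and Ccl4 were called higher, while Hopx stood at 0.793, Cxcr3 at 0.854 and Ccl5 at 1.45, and the median was -0.059 (-0.13 to 0.047). The interferon gamma response had a median of -0.061 (-0.13 to -0.023) over 21 members and none called, with Cxcl10 at 0.683 and Gbp10 at 1.22. Inhibitory receptor genes had a median of 0.14 (0.036 to 0.24) over 8 members at percentile 98.9, with Lag3 and Cd101, at 1.55, called higher.

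Among 7 cytotoxicity genes in Treg-like cells, with a median of 0.11, Ifng and the pore-forming Prf1 at 1.78 were higher and Gzmb lower. Among 12 memory and naive genes, with a median of 0.060, Ly6c2 was lower at 0.659 and Tcf7 stood at 1.31. Among 10 heat shock genes, with a median of -0.086, Hspa1b was lower. No member was called in the remaining lists, whose medians were -0.23 for 3 other helper genes, -0.19 for 4 T cell receptor activation genes, -0.10 for 8 proliferation genes, -0.060 for 16 glycolysis genes, -0.032 for 17 homing genes, -0.012 for 17 MHC class I genes, -0.00035 for 11 TGF-beta response genes, 0.0029 for 12 immediate early genes and 0.026 for 24 oxidative phosphorylation genes. Leaving out cells with proliferation genes, which removed most Treg-like cells, moved the medians of suppression genes to -0.065 and of Th1-like genes to -0.19. It turned those of the interferon gamma response to 0.075, of the type I interferon response to 0.010 and of cytotoxicity to -0.054. Genes of other cells were also seen in the class. Cd8a, chosen after its values were seen, had a ratio of 1.56 (1.2 to 2.04), with a UMI in 3.47% and 8.59% of cells unthinned, Cd8b1 stood at 1.06 and the macrophage gene Lyz2 at 0.408. In cluster 6, which was 12% of the non-responding and 15.3% of the responding class, Cd8a stood at 14.7 (4.61 to 75) and Ccl5 at 3.36 (2.38 to 4.81), also chosen after their values were seen. Cd8a was at 2.96 and 43.5 CPM there, so its ratio rests on few non-responding UMIs.

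In CD8 T-like cells the comparison asks whether the killer T cells of the same tumours differed too. The sums rest on 1282 cells with 14524349 UMIs and 1612 cells with 16244399 UMIs. Ifng was higher at 1.76 (1.63 to 1.89), as were the inhibitory receptor genes Lag3 at 1.72 (1.62 to 1.82) and Pdcd1 at 1.41 (1.34 to 1.48). Ifitm1 (ENSMUSG00000025491) was lower at 0.442 (0.428 to 0.456), the protease gene Gzma at 0.499 (0.476 to 0.523) and the chemokine receptor gene Ccr2 at 0.608 (0.570 to 0.649). Of 5396 measured genes, 98.6% lay within 1.5-fold, 9 were at least 2-fold higher and 3 at least 2-fold lower.

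The interval lay beyond 1.5-fold for 31 namable genes on the higher side and 4 on the lower. The 8 highest were Slc17a6, a vesicular glutamate transporter, at 2.5 (2.28 to 2.74), Igfbp7 at 2.42 (2.09 to 2.82), Sdcbp2 at 2.27 (1.97 to 2.62), the histone gene Hist1h2ap at 2.12 (1.86 to 2.43), Srgap3 at 2.08 (1.85 to 2.36), the glycine cleavage gene Gldc at 2.01 (1.71 to 2.37), the killer cell lectin receptor Klre1 at 2.01 (1.87 to 2.15) and Galnt3 at 1.98 (1.66 to 2.36). Slc17a6, Srgap3 and Klre1 are leading genes of cluster 11, which was larger in the responding class. Gzma leads cluster 14, which was 6.40% of the non-responding and 3.6% of the responding class, and Ifitm1 is among those of cluster 10, which was 66.8% and 54.3%. Gzma stood at 0.962 (0.870 to 1.06) within cluster 10, or 0.516 without the highest cells, and Ifitm1 stood at 0.473 (0.456 to 0.491) there. The lower ones also included the chemokine gene Cxcl10 at 0.487 (0.407 to 0.580), where 1 cell held 137 of the 362 UMIs of its library and the ratio without it was 0.667. Cd274 stood at 0.973, and Foxp3, at 0.639 (0.366 to 1.1), was at background level. Gm156 at 2.23, Gm10260 at 1.82 and Gm10076 at 2.65, chosen after their values were seen, lay beyond 1.5-fold outside the rule.

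After thinning, Lag3 was found in 22.1% of non-responding and 31.4% of responding CD8 T-like cells, 42.4% and 48.3% unthinned. Pdcd1 was found in 27.6% and 35.7%, 50.4% and 55.3% unthinned, Ifng in 16.2% and 22.8%, 36.7% and 41.9% unthinned, and Ccl4 in 25.2% and 28.5%, 39.4% and 42.9% unthinned. Gzmb was found in 39.4% and 39.6%, 55.0% and 53.6% unthinned. In CD4 conventional T-like cells Lag3 was found in 4.88% and 5.09%, 8.77% and 8.58% unthinned.

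All 11 inhibitory receptor genes lay above 1 in CD8 T-like cells, with a median log2 ratio of 0.49 (0.43 to 0.58), above each of the matched random lists. Lag3, Havcr2 (which encodes Tim3) at 1.77, Ctla4 at 1.54, the transcription factor Nr4a2 at 1.82 and Rgs16 at 1.57 were called higher. All 19 type I interferon response genes lay below 1, with a median of -0.29 (-0.35 to -0.22), below each of the random lists, and Rsad2 was called lower at 0.603. Of 8 T cell receptor activation genes, with a median of 0.34 (0.26 to 0.43), Spry2 at 1.60 and Ier3 at 1.93 were higher. Of 16 Th1-like genes, with a median of 0.21 (0.13 to 0.26), Ifng, Il12rb2 at 1.64, Ccl3 at 1.80 and Ccl4 at 1.68 were higher, and Cxcr3 stood at 0.728. Of 13 cytotoxicity genes, with a median of 0.16 (0.11 to 0.18), Ifng, Prf1 at 1.56 and Klrd1 at 1.57 were higher and Gzma lower, and Gzmk stood at 0.669. Prf1, Klrd1 and Gzmk are among the markers that named the class. Ccr2 was called lower among 15 homing genes, 14 of them below 1, with a median of -0.19 (-0.23 to -0.15).

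Cish, a STAT5 target, was lower at 0.622 among 9 genes of interleukin-2 signalling, with a median of -0.16. Irf8 was higher at 1.52 and Cxcl10 lower among 21 interferon gamma response genes, with a median of -0.080. Ctla4 was the called member of 6 Treg identity genes, median 0.23, and Havcr2 that of 11 suppression genes, median 0.18. No member was called among 12 immediate early genes with a median of 0.10, 17 MHC class I genes with 0.0089, 13 glycolysis genes with 0.00062, 24 oxidative phosphorylation genes with -0.0023, 14 memory and naive genes with -0.087, 7 TGF-beta response genes with -0.10, 15 proliferation genes with -0.13, 9 heat shock genes with -0.13 and 2 other helper genes with -0.21. An alternative added after seeing the data gave each cluster of the class the same weight in both libraries, set by its UMIs in both together. Clusters with few cells in either library were left out. With it, the inhibitory receptor median turned to -0.028, the type I interferon median to 0.036, the activation median to -0.060 and the suppression median to -0.032. It left 1 gene 2-fold higher and 0 lower. The log2 ratios of Slc17a6, Igfbp7, Srgap3, Gldc, Klre1 and Galnt3 then lay between 0.098 and 0.39, with Lag3 at 0.17, Pdcd1 at -0.018 and Gzma at -0.25. Sdcbp2 and Hist1h2ap stood at 0.77 each, Ifng at 0.35, Ifitm1 at -0.90, Cxcl10 at -0.35 and Ccr2 at -0.28. Within cluster 10 alone Ifng stood at 0.967, Pdcd1 at 1.01, Lag3 at 0.698 (0.602 to 0.809), and Gzmb at 0.663 (0.628 to 0.699). Within cluster 11 Ifng stood at 1.45 (1.32 to 1.61), Pdcd1 at 0.995 (0.933 to 1.06), Lag3 at 1.25 (1.17 to 1.35) and Gzmb at 1.40 (1.32 to 1.48). Within cluster 14 Ifng stood at 1.31 (0.849 to 2.01), Pdcd1 at 0.499 (0.291 to 0.823), Lag3 at 2.26 (1.07 to 4.87) and Gzmb at 1.22. Gzmb in these clusters was chosen after its values were seen.

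**Figure D3:**
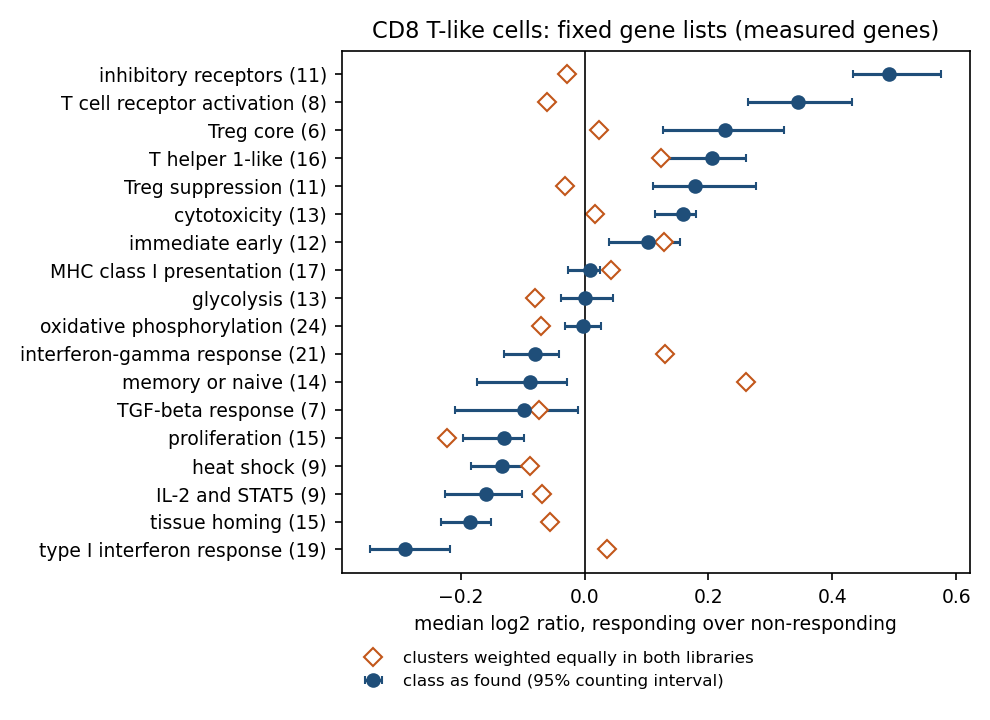
Median log2 ratio, responding over non-responding, of the fixed gene lists with more than 2 measured members in CD8 T-like cells, for the class as found (with 95% intervals for counting error) and with each cluster given the same weight in both libraries. Inhibitory receptor genes stood at 0.49 as found and at -0.028 when weighted.

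CD4 conventional T-like cells were compared with the same question, over 2179 cells with 16173371 UMIs and 2262 cells with 15072656 UMIs. The killer cell receptor genes Klrd1 (ENSMUSG00000030165) at 2.28 (2.07 to 2.51) and Klrk1 at 2.10 (1.88 to 2.34) were higher in the responding library. Ifitm1 was higher at 2.13 (2.07 to 2.19), with its relatives Ifitm2 and Ifitm3 at 1.59 each. Ccl4 was lower at 0.432 (0.410 to 0.455) and the cytokine gene Lta at 0.570 (0.497 to 0.653). Of 5510 measured genes, 99.5% lay within 1.5-fold, 5 were at least 2-fold higher and 1 at least 2-fold lower.

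The rule named 7 higher and 4 lower genes in this class. The others were the detoxifying enzyme gene Gstp1 at 1.96 (1.74 to 2.20), which was also higher in Treg-like cells at 1.76 (1.48 to 2.10) and CD8 T-like cells at 1.87 (1.64 to 2.12), and Ly6c1 at 1.69 (1.59 to 1.79), and on the lower side Arhgap31 at 0.508 (0.422 to 0.609) and the lamin gene Lmna at 0.530 (0.446 to 0.629). Ifitm1, Ifitm2 and Ifitm3 lead cluster 2, which was 29.6% of the non-responding and 35.5% of the responding class. Single cells held 2416 of 5024 non-responding and 1040 of 2021 responding Ccl4 UMIs, and the ratio without them was 0.404. The share of cells with a Ccl4 UMI was 4.45% and 4.60% unthinned and 2.44% and 2.28% thinned, and did not show the difference of the sums. In cluster 2 the Ccl4 ratio was 0.329, but 1.19 without the highest cells, and in clusters 7, 8 and 9 Ccl4 was below 20 CPM in both libraries. Ccl4 was among the leading genes of the small clusters 16.1, with 10 and 19 cells, and 16.2, with 14 and 8 cells. The class ratio thus does not describe most cells of the class. Ifng stood at 0.790 (0.742 to 0.840), but 1 cell of each library held 1441 of 2412 and 849 of 1775 UMIs, and without them the ratio was 1.02 (0.934 to 1.12). Foxp3 stood at 0.979, Pdcd1 at 0.903 (0.839 to 0.971), Lag3 at 1.15 (0.997 to 1.32) and Cd274 at 1.22 (1.1 to 1.34). AA467197 at 1.98, Gm10260 at 2.03 and Gm10076 at 2.88 lay beyond 1.5-fold outside the rule and were chosen after their values were seen.

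Proliferation genes were lower as a group in CD4 conventional T-like cells, with a median log2 ratio of -0.25 (-0.32 to -0.12) over 9 members and below each of the matched random lists. Mki67, which encodes the cycling marker Ki-67, at 0.642 and Mcm3 at 0.659 were called lower. Ccl3 at 0.623 and Ccl4 were lower among 15 Th1-like genes with a median of 0.048. Single cells held 606 of 1405 and 420 of 816 Ccl3 UMIs, the ratio without them was 0.532, and cells with a Ccl3 UMI, unthinned, were more frequent in the responding library, at 2.92% against 1.42%. Lta was lower among 13 interleukin-2 signalling genes with a median of -0.085, and Ccr4, at 0.667, was lower among 17 homing genes with a median of -0.11. Klrk1 and Klrd1 were higher among 10 cytotoxicity genes with a median of -0.011. No member was called among 12 immediate early genes with a median of 0.11, 19 interferon gamma response genes with 0.041, 17 MHC class I genes with 0.031, 24 oxidative phosphorylation genes with 0.0031, 14 glycolysis genes with -0.016, 8 TGF-beta response genes with -0.046, 10 heat shock genes with -0.051, 8 activation genes with -0.063, 13 memory and naive genes with -0.069, 8 inhibitory receptor genes with -0.072, 11 suppression genes with -0.086, 19 type I interferon response genes with -0.10, 9 Treg identity genes with -0.11 and 2 other helper genes with -0.16.

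Cells with 2 or more thinned UMIs of the proliferation list were 79.4% of Treg-like cells in both libraries, 77.8% and 75.9% of CD8 T-like cells and 77.5% and 76.2% of CD4 conventional T-like cells. Unthinned, these shares were 92.8% and 91.7%, 98.6% and 97.5%, and 93.9% and 91.7%. The list holds broadly expressed genes such as Tubb5. Cells with a thinned Mki67 or Top2a UMI, a measure added after seeing this, were 20.2% and 19.1%, 20.4% and 17.8%, and 16.3% and 13.7% of the 3 classes, and 31.9% and 27.6%, 43.9% and 36.8%, and 29.2% and 23.7% unthinned.

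Surface antibody counts ask whether protein levels set the classes apart. They were compared within each library only, since the median per used cell was 314 counts in the non-responding and 5 in the responding library, where 432 cells (7.13%) had none. Treg-like cells held 11.8-fold (11.4 to 12.2) more CD25, the interleukin-2 receptor alpha chain, than CD4 conventional T-like cells in the non-responding library and 19.3-fold (13.3 to 28.7) more in the responding one. The integrin CD103 was 9.06-fold and 5.51-fold (4.69 to 6.49) higher, the costimulatory receptor 4-1BB 6.19-fold and 4.61-fold, ICOS 1.55-fold and 1.70-fold, and CD27 1.82-fold and 1.83-fold. PD-1 stood at 0.961 and 1.70 in the same comparison. The animals had been given antibodies against PD-1 and LAG-3, and whether these changed the counts of those 2 receptors was not tested. As centred log ratios, the responding differences of CD25, CD103 and 4-1BB were 0.15, 0.26 and 0.16 on the log2 scale, and that of PD-1 turned to -0.061. CD8 T-like cells held 19.3-fold and 20.1-fold more CD8a, 2.88-fold and 6.10-fold more Tim3 and 1.70-fold and 2.93-fold more PD-1 than CD4 conventional T-like cells.

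Cluster 11 held more of several receptors than cluster 10. Tim3 was 8.16-fold and 9.83-fold (6.85 to 14.5) higher, PD-1 3.40-fold and 3.92-fold, and 4-1BB 5.76-fold and 7.30-fold, while CD127, the interleukin-7 receptor, stood at 0.541 and 0.312. LAG-3 was 2.63-fold higher in the non-responding library and 9.29-fold (2.69 to 49.5) in the responding one, where it rests on 17 and 3 counts and as a centred log ratio turned to -0.025 on the log2 scale. The Il1rl1 cluster kept out of the CD4 class held 4.27-fold and 4.16-fold more 4-1BB, 2.34-fold and 2.22-fold more ICOS, and CD27 at 0.268 and 0.528, relative to CD4 conventional T-like cells. Its surface CD3 stood at 1.11 and 1.42 and its CD4 at 0.910 and 0.760 in the same comparison. More CD4 than CD8a was counted on 99.5% and 90.7% of Treg-like cells and 97.8% and 91.9% of CD4 conventional T-like cells, and more CD8a than CD4 on 90.5% and 77% of CD8 T-like cells, with more CD4 on 9.28% and 6.64% and equal counts on 3 and 263 cells. Equal counts were found on 0 and 71 Treg-like cells and on 2 and 127 CD4 conventional T-like cells.

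Summed markers of other cells in the 3 T cell classes had responding over non-responding ratios of 0.974 for gamma-delta T cells, 1.14 for natural killer cells, 0.776 for innate lymphoid cells, 0.657 for B or plasma cells (77.2% of it Ighm), 0.977 for macrophages or monocytes (83.5% Ly6c2, which T cells also express), 0.960 for neutrophils, 0.625 for dendritic cells, 0.672 for mast cells or basophils, 0.747 for CT26 tumour cells, 0.807 for fibroblasts or endothelium (98.1% Pecam1) and 1.09 for erythroid cells. Gzma made up 34.4% of the natural killer sum and Gata3 43.9% of the innate lymphoid sum. Each sum pools the 3 classes, whose mix differed between the libraries, so its ratio may also follow that mix. Lyz2, chosen after its values were seen, stood at 0.408, 0.419 and 0.475 in Treg-like, CD8 T-like and CD4 conventional T-like cells. The markers of each class in its own cells, which named it, had ratios of 0.906, 0.977 and 0.949.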

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

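The tests of a few cells and of free RNA in the Ccl4 pattern, of a single clone in the cluster 11 pattern and of library preparation in the gene model pattern were chosen only after the results had been seen. The free RNA test replaced an earlier one on the Ccl4 ratio in CD4 conventional T-like cells, which their own Ccl4 would hide.

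Some ratios pointed in opposite directions in different classes. Ccl4 had a responding over non-responding ratio of 6.77 in Treg-like and 1.68 in CD8 T-like cells but 0.432 in CD4 conventional T-like cells. Ifitm1 stood at 2.77 in Treg-like and 2.13 in CD4 conventional T-like cells but at 0.442 in CD8 T-like cells. The differences between classes were not tested, and single cells weigh on Ccl4 and on Ifitm1 in Treg-like cells. In CD4 conventional T-like cells Ccl4 was low in the large clusters and led the small clusters 16.1 and 16.2. Its ratio there does not describe most cells of the class. T cell receptor segments, which no comparison used, also gave a signal above the limit that a count of 0 allows. Trbv3 was found in 33.6% and Trav6n-6 in 34.5% of non-responding cluster 11 cells that held any beta or alpha segment.

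Ccl4 and Ifng sums were higher in responding Treg-like cells. Without the 3 highest cells of each library Ccl4 stood at 3.29 (2.31 to 4.73) and Ifng at 1.91 (1.26 to 2.89). These intervals leave out the spread of UMIs between cells. A few cells as the whole cause is argued against for Ccl4. Its thinned share of cells was 1.66% (1.03 to 2.53) in the non-responding and 4.74% (3.34 to 6.51) in the responding library. For Ifng a few cells cannot be told apart, because its thinned shares, 1.82% and 2.77%, had overlapping intervals. Free RNA as the whole cause is argued against for Ccl4, found after thinning in 2.28% (1.69 to 3.02) of responding CD4 conventional T-like cells and in 4.74% (3.34 to 6.51) of Treg-like cells, but cannot be told apart for Ifng, where 7.56% (6.47 to 8.78) of the CD4 cells, which may express it, exceeded the Treg-like share of 2.77%. Doublets with CD8 T cells cannot be told apart either, because 2 of the 5 responding cells with most Ccl4 UMIs held Cd8a or Cd8b1 UMIs. The highest held 32 of them beside 10 Foxp3, 282 Ccl4 and 33 Ifng UMIs. The Cd8a ratio of 14.7 (4.61 to 75) in Treg-like cluster 6 says little on this. Ccl4 was at 3.94 and 9.23 CPM in that cluster, against 15.1 and 110 CPM in cluster 5. A difference that goes with response stays open and was not tested.

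Cluster 11 was a larger share of responding CD8 T-like cells. Depth as the whole cause is argued against, since after thinning the share of class cells with 3 or more UMIs of its leading genes was 16% and 33.7%, a ratio of 2.11 (1.83 to 2.44), although these genes were chosen from the cluster. A single expanded clone as the whole cause is argued against. The commonest beta segment, Trbv13-2, was in 22.3% (17.7 to 27.4) of the responding cluster cells with a beta segment. A clone behind part of the gain stays open. The alpha segment Trav3-3, chosen after its values were seen, was in 27.8% of the responding cluster cells with an alpha segment. It was in 11.2% of such cells of non-responding cluster 11 and 10.8% of those of responding cluster 10. Doublets or free RNA cannot be told apart, because 9.22% (7.20 to 11.6) of the cluster's cells held a Cd4 or Foxp3 UMI, with an interval that crosses the 10% bound set for the test, against 8.77% in the other CD8 T-like clusters, while the cluster's median doublet score lay at percentile 15.5 of those clusters. A difference that goes with response stays open and was not tested.

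Gm10076 and Gm10260 were higher in every class and cluster examined of the responding library. The lowest Gm10076 ratio of 9 classes and clusters was 1.99 (1.56 to 2.54) and the highest 3.25, and those of Gm10260 were 1.48 (1.07 to 2.03) and 2.15. A difference between the library preparations cannot be told apart from one that goes with response, since each group is 1 library and both would give a gain in every class. Reads shared with ribosomal protein genes cannot be told apart, because the test cannot decide it: the 2 gene models were 0.169% to 0.391% of their sum with the ribosomal protein genes, and in the class farthest from 1 the ratio of that sum was 1.07 with them and 1.07 without. A difference that goes with response stays open and was not tested.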

How the results depend on the processing

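Tests chosen only after the data were seen were clustering with all variable genes, sums without each gene's highest cell and clusters given the same weight in both libraries. Cells with a Mki67 or Top2a UMI left out, and Mki67 or Top2a as the proliferation measure, were also chosen then. So were clustering without the 40 genes of the cluster 11 check, and centred log ratios of antibody counts between clusters. No paired analysis was possible because each group is 1 library. Of the results that answer a comparison, 118 values under alternatives stayed within their counting interval or, for counts of genes, within 1.5 times the count, 74 moved and 3 reversed. Of the other results 845 stayed, 302 moved and 24 reversed. A higher resolution and a stricter mitochondrial limit left each class share and ratio within its interval. No scaling moved the median of all genes by over 0.1 on the log2 scale. Depth limits genes near 20 CPM and antibody counts of the responding library. Where a value moved, the cause was not tested unless named.

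Classes from each cell's own UMIs gave folds of 0.575 for Treg-like, 1.22 for CD8 T-like and 0.934 for CD4 conventional T-like shares, CD8 to Treg ratios of 1.72 and 3.66, 12 higher and 7 lower Treg-like genes, 1 lower CD8 T-like gene, 8 lower genes in CD4 conventional T-like (CD4) cells and an immediate early median of -0.037 in CD4 cells. Doublets kept gave a CD8 T-like fold of 1.19, ratios of 0.841 and 1.59, 3 higher and 0 lower CD8 T-like genes, 0 lower CD4 genes, a memory median of 0.050 in CD8 T-like and a heat shock median of 0.0076 in CD4 cells. The lower resolution gave ratios of 1.15 and 2.29. Clustering without Treg genes gave 1.14 and 2.21, with 15 higher and 1 lower CD8 T-like genes. Clustering with all variable genes gave 1.09 in the non-responding library.

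A mean over cells gave 4 higher Treg-like genes, 0 lower CD4 genes, memory medians of -0.0058 in Treg-like and 0.035 in CD8 T-like cells and an inhibitory receptor median of 0.0067 in CD4 cells. Measurement at 10 CPM gave 11 higher and 9 lower Treg-like, 16 and 5 CD8 T-like, and 8 and 4 CD4 genes, as more genes entered. At 50 CPM, with fewer genes, 2 and 0 Treg-like genes and 4 higher CD8 T-like genes were left, and the CD8 T-like activation median was -0.030. Median-of-ratios scaling gave 1 lower CD8 T-like gene. CPM without ribosomal, mitochondrial and receptor genes gave 2 lower Treg-like, 18 higher CD8 T-like, and 10 higher and 2 lower CD4 genes, with an inhibitory receptor median of 0.0082 in CD4 cells.

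Leaving out cells with 2 or more thinned UMIs of proliferation genes removed most cells. It had first been defined on unthinned UMIs, which left almost none, and was redefined after this was seen. It gave 55 higher and 49 lower Treg-like, 29 and 9 CD8 T-like, and 11 and 7 CD4 genes. Treg-like medians were -0.065 for suppression, -0.19 for Th1-like, 0.075 for interferon gamma response, 0.010 for type I interferon response and -0.054 for cytotoxicity genes, with log2 ratios of -0.87 for Trdc and -0.97 for Mt1. CD8 T-like medians were -0.11 for immediate early and 0.042 for proliferation genes. Leaving out cells with a Mki67 or Top2a UMI instead gave 5 lower Treg-like genes, 24 higher and 1 lower CD8 T-like genes and a Treg-like Ifitm1 log2 ratio of -0.064. Without each gene's highest cell, 3 Treg-like genes were higher.

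With each cluster given the same weight in both libraries, 1 CD8 T-like gene was higher and 0 lower. The CD8 T-like medians were then -0.032 for suppression, 0.00069 for other helper, 0.13 for interferon gamma response, 0.036 for type I interferon response, -0.028 for inhibitory receptor, 0.26 for memory and -0.060 for activation genes. In CD4 cells 2 genes were higher and the MHC class I median was -0.0036. Cells with a Mki67 or Top2a UMI had share folds of 0.947, 0.872 and 0.842 in Treg-like, CD8 T-like and CD4 cells, and with 4 or more UMIs of the list the folds were 0.919 in CD8 T-like and 0.926 in CD4 cells. As centred log ratios on the log2 scale, the differences between Treg-like and CD4 conventional T-like cells were 1.63 for CD25, 2.03 for CD103, 1.11 for 4-1BB, 0.053 for ICOS, 0.42 for CD27 and -0.67 for PD-1 in the non-responding library and 0.15, 0.26, 0.16, 0.23, 0.076 and -0.061 in the responding one, where cells hold a median of 5 counts. Between CD8 T-like and CD4 cells they were 4.67 for CD8a, 0.47 for Tim3 and 0.42 for PD-1, and 1.52, 0.16 and 0.11. Between clusters 11 and 10 the responding LAG-3 difference was -0.025.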

Other observations

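No test in this part was chosen after its result had been seen, but the clusters and genes were chosen after their values were seen. Within cluster 11, type I interferon response genes were higher in the responding library, with a median log2 ratio of 0.85 (0.67 to 0.93), 11 of 15 members at least 1.5-fold higher, and Ifit1, an RNA-binding antiviral protein, at 4.98 (3.40 to 7.56) and the ubiquitin-like Isg15 at 2.59 (2.15 to 3.15). Proliferation genes were lower there, with a median of -0.78 (-0.93 to -0.52), 8 of 15 members lower, Mki67 at 0.449 and the replication helicase gene Mcm5 at 0.358. In the same cells Eomes, a transcription factor of memory and killer cells, stood at 0.401, Gzmb at 1.40 and Ifng at 1.45. The genes of these lists, Gzmb and Ifng were left out of the clustering, but Eomes, on the natural killer list, was not. Other interferon and cell cycle genes could stay in. CD8 T-like clusters led by such genes formed apart, so cluster 11 may itself be selected on both programs.

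Cluster 9, CD4 conventional T-like cells led by Lef1 and Ccr7, was 14% of the non-responding and 8.80% of the responding class, and its interferon gamma response genes had a median of -0.59, with 9 of 18 members lower, among them Gbp5 at 0.423. Cluster 15, unnamed and led by Zbtb16 and Il4, had a proliferation median of -0.88 with 6 of 10 members lower, Mki67 at 0.324 and Cxcl10 at 3.97. In the unnamed cluster with natural killer receptor genes the type I interferon median was 0.31 with 4 of 21 members higher, Ifitm1 stood at 6.12 and the receptor-induced genes Egr1 at 0.406 and Egr3 at 0.224. In the Il1rl1 cluster kept out of the CD4 class, Areg, a growth factor of tissue repair, stood at 3.36 and the histamine enzyme gene Hdc at 0.286.

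In non-responding cluster 11, Trbv3 was held by 38 of 113 cells with a beta segment and Trav6n-6 by 40 of 116 with an alpha segment, against 4.98% and 2.85% in the responding cluster 11 and 2.23% and 3.91% in non-responding cluster 10. A candidate explanation is 1 clone that holds both. Of Trbv3 cells with an alpha segment, 18 of 20 (90%, 68.3 to 98.8) held Trav6n-6, against 9 of 52 (17.3%, 8.23 to 30.3) of the other cells, which is not under the 10% set for the test, so it stays open. That such a clone gives the proliferation and interferon differences of cluster 11 is argued against, since without cells holding either segment (122 and 510 cells left) the medians were -0.83 (-0.96 to -0.58) and 0.72 (0.60 to 0.89).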
